A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

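Total RNA from log-phase cultures of 3 strains of Saccharomyces cerevisiae (BY4741, its eos1 deletion and its izh2 deletion) was isolated with hot phenol, labelled with biotin and hybridised to Affymetrix Yeast Genome 2.0 arrays, per the labels' protocols. Cultures were grown in the rich medium YPD at 30 degrees Celsius with shaking at 150 rpm to an optical density of 1.0 at harvest, per the labels. The labels describe 2 independent experiments, and each strain has 2 arrays, 6 in all. They do not say whether same-numbered arrays of different strains share a day or a batch.

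The authors deposited 1 signal intensity per probe set and array on a linear scale, for 10928 probe sets. Per the submitters' processing notes the software was GCOS, whose version is not given in the sources used here, and per the series' design text the authors' statistics were done in GeneSpring 7.3.1. How the deposited signal intensity was scaled between arrays is not given in the sources used here. The arrays' medians differed: over all probe sets they were 37.6 and 35.7 in the wild type, 62.2 and 47.7 in the eos1 deletion and 37.3 and 33.7 in the izh2 deletion. The median of 9 probe sets for hybridisation controls, on the log2 scale, differed by -0.004 between the eos1 deletion and the wild type and by -0.08 between the izh2 deletion and the wild type. No array image or probe-level file was used here.

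Probe sets were named through the platform annotation and the gene table of the R64 assembly. That table was used for names, neighbours, the assignment of genes to chromosomes and the order of genes along chromosome II. Its start positions served only for that order, and the sources used here name no build. Of the probe sets 5498 name 1 gene of S. cerevisiae, 1 names several genes, 1746 name a gene outside the S. cerevisiae table and 3683 name none, among them 166 control probe sets. Of the gene symbols 12 were updated. For 47 genes with more than 1 probe set, the probe set with the highest mean log2 signal over all arrays was used. Of these genes 33 had at least 2 probe sets above the filter, and in 0 of them the probe sets differed by more than 1 in the log2 fold change of the eos1 deletion.

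Deposited signals were floored at 1, transformed to log2 and fitted without further normalization, as fixed before the data were examined. A gene was tested if its mean log2 signal over all 6 arrays lay above the 95th percentile of that of the probe sets naming no S. cerevisiae gene (6.52, a signal of 91.8), which kept 4907 of 5449 genes, 90.1%. Linear models were fitted to all 6 arrays together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend), so that the 3 strains share 1 estimate of the spread with 3 residual and 7.41 prior degrees of freedom. P values were two-sided and adjusted over the tested genes of a comparison by the Benjamini-Hochberg method, with 0.05 as the threshold. Since the fit used signals that the authors may not have brought to a common scale, counts are also given after each array was centred on its median, and list medians relative to the median of all tested genes. Arrays are separate experiments per the labels, so that the p values of single genes measure the spread between experiments as far as the labels go.

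Gene lists, 29 in all, were fixed at the same time: the Zap1 zinc regulon, zinc transport, the IZH family, the phosphate starvation, iron and copper responses, the unfolded protein response, N-glycosylation, oxidative, general and heat stress, ribosomal proteins, ribosome biogenesis, ergosterol, phospholipid and fatty acid synthesis, peroxisomal beta-oxidation, methionine and sulfur assimilation, amino acid synthesis, glycolysis, respiration, glucose-repressed genes, cell wall integrity, histones, a-cell and alpha-cell genes, the auxotrophic markers and the neighbours of each deleted gene. Lists with at least 5 tested members, 24 of them, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, EOS1 and IZH2 left out, and adjusted over the lists. With an estimated correlation camera rests on the 3 residual degrees of freedom and has little power. A call lost there does not show that a list was unchanged. At the preset correlation camera compares the genes of a list with other genes. Those p values do not measure the spread between experiments. They come out too small where the genes of a list vary together by more than the preset value. Fry was run beside camera on median-centred values, its p adjusted over the lists. It tests whether the genes of a list shift, on balance, in 1 direction and does not compare them with other genes. The symbols named in the text follow a rule set beforehand: the deleted genes, the 8 highest and 8 lowest log2 fold changes among called genes whose mutant arrays lie beyond the wild-type arrays (for want of calls, up to 8 per direction with the smallest p), up to 4 members with the smallest p of each called list and of the Zap1 list, the neighbours and the markers, the 4 highest and 4 lowest between the deletions, and up to 6 genes called in both deletions. Other named genes are said to be chosen after their values were seen.

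The fit was tested on 20 simulated sets of the comparison of the eos1 deletion with the wild type, with 4907 genes of which 200 were changed. It recovered 72.2% of 2-fold and 99.85% of 4-fold changes, with a mean of 11.1 false calls per set, and made a mean of 0.5 calls where nothing was changed. Camera found 20 of 20 shifted lists and called 2 of 380 unshifted ones. The simulated genes varied independently and their lists were drawn at random. These counts therefore say nothing on lists whose genes vary together. Tests were repeated with quantile normalization, median centring, no filter or a stricter filter at the 40th percentile, a pseudocount of 16 in place of the floor, other eBayes settings, the median of a gene's probe sets, a replicate block, only the 4 arrays compared, a 2-fold rule without a test or beside it, and each array left out in turn, where a strain left with 1 array is assumed to vary like the others. Fits without chromosome II genes were added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Groups of 2 arrays are too small for counting other splits of the samples.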

Results

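Transcript levels were measured on 6 oligonucleotide arrays in log-phase cultures of the haploid budding yeast BY4741, a laboratory strain of mating type a that lacks HIS3, LEU2, MET17 and URA3 function. The wild type was compared with a derivative lacking EOS1 and with a derivative lacking IZH2, with 2 arrays per strain from separate experiments. EOS1 encodes a membrane protein of the endoplasmic reticulum linked to N-glycosylation and to tolerance of oxidative stress, and IZH2 encodes a membrane protein linked to zinc metabolism. The title of the series places the comparison in the study of zinc homeostasis. Values were probe set signals on a linear scale. The median signal of the 4907 genes tested was 644 and 589 on the wild-type arrays, 792 and 660 on the eos1 deletion arrays, and 581 and 554 on the izh2 deletion arrays. Across genes, which are not independent replicates, the log2 signals of the 2 arrays of a strain correlated at r = 0.969 in the wild type, 0.976 in the eos1 deletion and 0.981 in the izh2 deletion. The number of arrays limits the precision of every value below.

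The deleted genes were examined first. EOS1 (YNL080C) had a signal of 693 ± 1.40 (SD, n = 2) in the wild type and 718 ± 167 (SD, n = 2) in the izh2 deletion, but 0.42 and 2.70 on the eos1 deletion arrays, below the background of both arrays. EOS1 was at least 51.6-fold lower in its own deletion than in the wild type (limma, adjusted p = 6.2e-06). IZH2 (YOL002C) had a signal of 2967 ± 816 (SD, n = 2) in the wild type and 3.46 and 1.12 on the izh2 deletion arrays, again below background, and was at least 284-fold lower (limma, adjusted p = 2.0e-06). Background was the 95th percentile, on each array, of the probe sets that name a gene of another organism, and a dim gene was set at that level for these bounds. The genes next to each deleted gene gave no call: in the eos1 deletion the log2 fold changes of SWS2 and TPM1 were 0.11 and 0.07, and in the izh2 deletion those of PHO80 and PFA4 were -0.08 and -0.45. All except that of PFA4 took the other sign after median centring. Of the auxotrophic markers, LEU2, MET17 and URA3 did not pass the filter on dim genes, with mean wild-type signals of 22.1, 7.30 and 3.78. HIS3 gave signals in all strains, 2273 ± 211 (SD, n = 2) in the wild type, with log2 fold changes of -0.53 in the eos1 deletion and -0.36 in the izh2 deletion that did not pass the test.

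The first comparison asked how loss of EOS1 altered the transcriptome. The falls included phosphate-responsive genes and genes of mating-type a cells. The rises included stress-protective genes and 207 of the 352 tested genes of chromosome II, or 158 after median centring. Camera called 12 of 24 gene lists, and 0 with an estimated correlation. PHO11, an acid phosphatase, dropped from a signal of 5624 ± 45.5 to 399 ± 51.1 (SD, n = 2 each), a 14.2-fold fall (adjusted p = 6.9e-06). MFA1, a gene for the a-factor pheromone, fell 8.05-fold, from 3533 ± 1110 to 472 ± 281 (adjusted p = 0.0035). Its fall was 12.6-fold without the first eos1 deletion array and 5.14-fold without the second. HSP26, a small heat shock protein encoded on chromosome II, rose 11.8-fold, from 340 ± 53.5 to 4174 ± 1740 (adjusted p = 0.00058). In all, 349 genes passed an adjusted p under 0.05, 314 higher and 35 lower, and in each of them both mutant arrays lay beyond both wild-type arrays.

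The median of all tested genes was itself 0.21 higher in the eos1 deletion on the log2 scale. After each array was centred on its median, 317 genes passed, 207 higher and 110 lower, of which 242 were among the 349. The share of calls that were higher went from 90.0% to 65.3%. Outside chromosome II the direction turned over, from 107 higher and 34 lower to 49 higher and 108 lower after median centring. Changes of gene lists are therefore given below relative to the median of all tested genes. Without the first eos1 deletion array 159 genes passed, and without the first or the second izh2 deletion array, which enter only through the shared estimate of the spread, 224 and 225 passed.

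Genes of chromosome II stood apart from the rest of the genome in the eos1 deletion. The 352 tested genes of this chromosome had a median log2 fold change of 1.03 (quartiles 0.75 and 1.28), against 0.19 (quartiles -0.04 and 0.41) for the 4555 genes of the other chromosomes. The excess of 0.85 corresponds to 1.80-fold. It was 0.85 on the first eos1 deletion array and 0.84 on the second, against -0.02 and -0.01 on the izh2 deletion arrays, each measured against the mean of the wild-type arrays. Of the chromosome II genes, 93.5% lay above the median of the other genes. Chromosome II held 207 of the 314 higher calls (65.9%) and 1 of the 35 lower ones, and without the first eos1 deletion array 80 of its genes rose. The largest departure of any other chromosome from the rest was 0.08. Fitted without chromosome II genes, an alternative added after the data were examined, 59 genes passed, 38 higher and 21 lower. After median centring 100 passed, 33 higher and 67 lower. The 59 were all among the 349, which held 107 higher and 34 lower genes of other chromosomes. The adjusted p of genes on other chromosomes thus depended in part on the chromosome II calls. Which named genes kept their call without them is not given here.

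**Figure D1:**
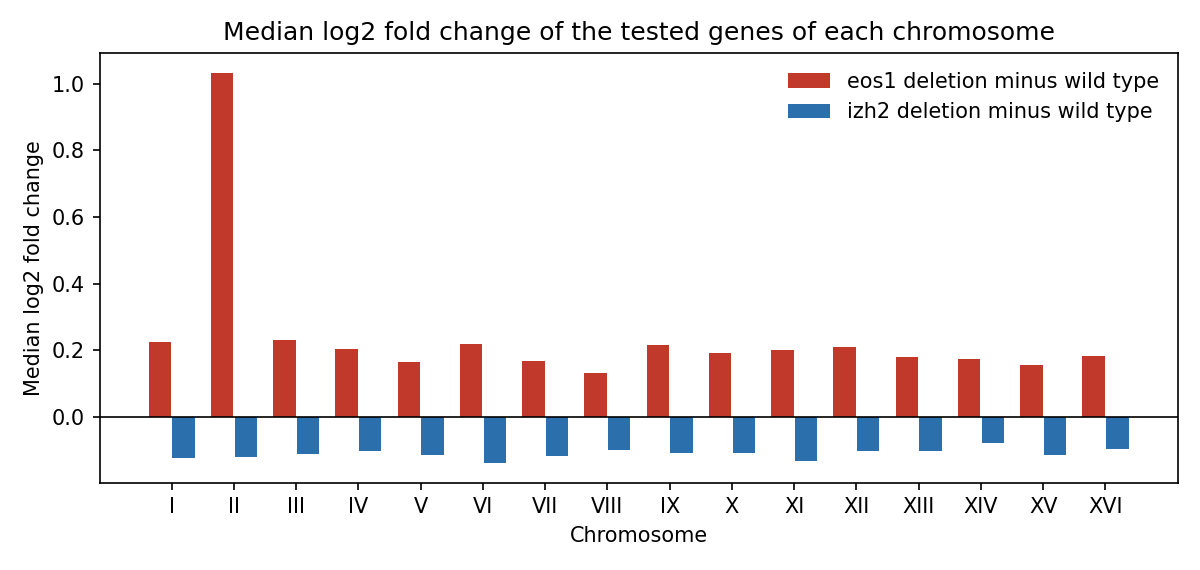
Median log2 fold change against wild type (vertical axis) of the tested genes of each of the chromosomes (horizontal axis), with red bars for the eos1 deletion and blue bars for the izh2 deletion. The bar of chromosome II in the eos1 deletion stands at 1.03, and the median over all other chromosomes is 0.19.

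Beyond chromosome II, the genes with the largest rises among those called were DDR2 (7.54-fold, adjusted p = 0.0038) and HSP12 (7.06-fold, adjusted p = 0.0039), both induced by many stresses, NQM1, a transaldolase paralogue (7.04-fold), NCA3 (6.87-fold), the vacuolar mannosidase gene AMS1 (5.09-fold) and RTC3 (4.79-fold). SDS24, on chromosome II, rose 5.08-fold. Without the first eos1 deletion array DDR2 rose 4.98-fold and HSP12 4.34-fold, and without the second 11.4-fold and 11.5-fold. Among the falls, after EOS1 itself, came PHO11, PHM6, SPL2, MFA1, the cell fusion gene FUS1, the ribosomal protein gene RPS9A (4.11-fold, adjusted p = 0.0038) and YAR068W (3.77-fold, adjusted p = 0.0065).

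Of 14 tested genes of the phosphate starvation (PHO) regulon, which serves phosphate scavenging and storage, 5 fell and 0 rose, and 9 fell after median centring. Adjusted over the list alone, 11 fell and 1 rose. PHM6 fell 10.5-fold (adjusted p = 0.0019), SPL2 fell 8.40-fold (adjusted p = 0.0011) and PHO5, the secreted acid phosphatase, fell 2.55-fold (adjusted p = 0.0067) although it lies on chromosome II. PHO84, the high-affinity phosphate transporter, had a log2 fold change of -0.37 that did not pass (adjusted p = 0.15). The median of the list was -0.94 relative to all genes (camera, adjusted p = 1.1e-18). With an estimated correlation the call was lost (adjusted p = 0.17).

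Genes of a-cells and of the pheromone response formed the list with the lowest median, -1.33 relative to all genes. Of 14 tested members 10 fell and 0 rose, and 12 fell adjusted over the list alone. Without the first eos1 deletion array 6 of them fell. FUS1 fell 4.34-fold (adjusted p = 0.0025), BAR1, the protease that degrades alpha-factor, fell 3.25-fold (adjusted p = 0.0038) and MFA2, the other a-factor gene, fell 2.67-fold (adjusted p = 0.0041). Camera called the list lower (adjusted p = 1.3e-20), a call lost with an estimated correlation (adjusted p = 0.14). Of the alpha-cell marker list 1 of 4 genes passed the filter, SAG1, with a log2 fold change of 0.67 (adjusted p = 0.099).

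**Figure D2:**
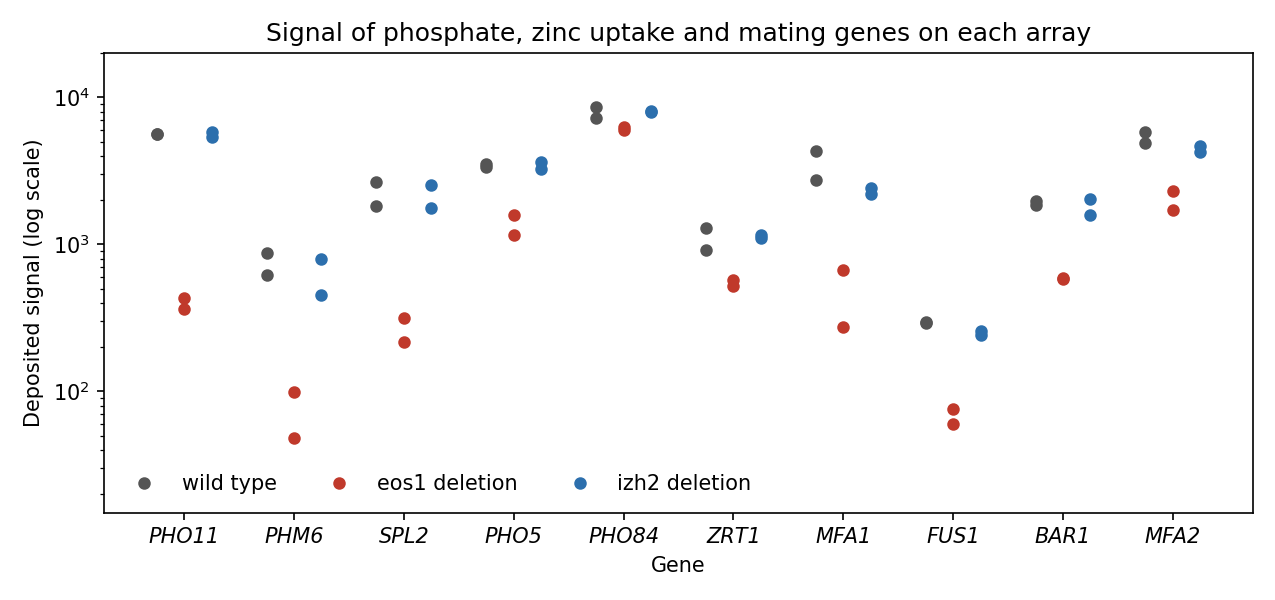
Deposited signal on each array (vertical axis, log scale) of phosphate-responsive genes, the zinc transporter gene ZRT1 and mating genes (horizontal axis), with a point for each of the 2 arrays of a strain. For PHO11 the eos1 deletion arrays average 399 against 5624 in the wild type and 5605 in the izh2 deletion.

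Of 26 tested general stress genes controlled by Msn2 and Msn4, 13 rose and 0 fell, 20 rose adjusted over the list alone, and 6 rose after median centring. Beside HSP26, DDR2 and HSP12, the glycoprotein gene YGP1 rose 2.74-fold (adjusted p = 0.0098). The list's median was 0.83 relative to all genes (camera, adjusted p = 6.3e-10), with an adjusted p of 0.715 with an estimated correlation. Of its tested members 24 lay outside chromosome II, and their median was 0.82. Without the first eos1 deletion array 4 of the general stress (Msn2/4) genes rose, and 8 without the first or without the second izh2 deletion array.

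Of 15 tested genes of the unfolded protein response, 3 rose and 0 fell, and 8 rose adjusted over the list alone. The oxidase gene ERO1 rose 2.02-fold (adjusted p = 0.021), SIL1, a nucleotide exchange factor for the chaperone Kar2, rose 2.07-fold (adjusted p = 0.032) and DER1, a component of protein degradation at the endoplasmic reticulum that lies on chromosome II, rose 2.21-fold (adjusted p = 0.048). HRD1 had a log2 fold change of 0.71 (adjusted p = 0.077). After median centring the adjusted p of SIL1 was 0.051 and that of DER1 0.067, and without the first eos1 deletion array ERO1, SIL1 and DER1 had adjusted p of 0.16, 0.18 and 0.23. The call of ERO1 was also lost without the first wild-type array, and those of SIL1 and DER1 without the second wild-type array or 1 of the izh2 deletion arrays, at lower adjusted p than these. Camera called the list higher (median 0.37 relative to all genes, adjusted p = 0.0068), with an adjusted p of 0.715 with an estimated correlation. The median was 0.21 without the first wild-type array. Of 29 tested N-glycosylation genes 5 rose and 0 fell (6 rose adjusted over the list alone), and the list was not called (camera, adjusted p = 0.22, and 0.045 under a stricter filter on dim genes). The 5 N-glycosylation genes, named after their values were seen, were ROT2, ALG1, RER2, ALG3 and ALG7, with log2 fold changes from 0.95 to 1.25. All lie on chromosome II, and 0 of the 23 members outside it rose. After median centring 3 members of the list rose. Leaving out single arrays gave 4 without the first wild-type array, 3 without the second eos1 deletion array, 2 without the second wild-type array or 1 of the izh2 deletion arrays, and 1 without the first eos1 deletion array.

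Of the zinc genes 1 was called. ZRT1, the high-affinity zinc uptake transporter, fell 2.01-fold, from 1110 ± 270 to 545 ± 39.2 (SD, n = 2 each; adjusted p = 0.033), and it was the 1 called gene among the 23 tested members of the Zap1 zinc regulon, also when adjusted over the list alone. This call was lost on leaving out any of the arrays except the second wild-type one, with adjusted p up to 0.17. IZH4 had a log2 fold change of -1.02 (adjusted p = 0.11, and 0.031 after median centring), ZAP1, the zinc-responsive activator itself, 0.62 (adjusted p = 0.21) and the catalase gene CTT1 1.08 (adjusted p = 0.14). CTT1 passed at 1.40 without the first wild-type array (adjusted p = 0.017) and at 1.65 without the second eos1 deletion array (adjusted p = 0.020), and had 0.52 without the first (adjusted p = 0.61). IZH4 passed at -1.35 without the second wild-type array (adjusted p = 0.012) and at -1.54 without the first eos1 deletion array (adjusted p = 0.025), and had -0.51 without the second (adjusted p = 0.39). The regulon had a median log2 fold change of -0.02, or -0.23 relative to all genes. Camera called it lower (adjusted p = 0.013), and the adjusted p was 0.715 with an estimated correlation and 0.13, at a median of -0.12, without the second eos1 deletion array. On median-centred values fry of limma gave an adjusted p of 0.038 for a shift of the regulon in 1 direction, and 0.056 for the zinc transport list. For other lists called by camera, fry gave 0.0037 (phosphate starvation), 0.0065 (a-cell), 0.013 (ribosome biogenesis) and 0.030 (unfolded protein response). Its adjusted p was 0.093 for the general stress genes. It lay between 0.15 and 0.23 for the ribosomal protein, methionine and sulfur, amino acid synthesis, glycolysis and fatty acid lists. Among 10 tested zinc transport genes 1 fell, ZRT1, also when adjusted over the list alone. That list's median was -0.40 relative to all genes (camera, adjusted p = 0.0068; adjusted p = 0.49 with an estimated correlation), and the adjusted p was 0.055 without the second wild-type array and 0.061 without the first eos1 deletion array. FET4 and MSC2, of this list, had log2 fold changes of -0.40 and 0.45 that did not pass. Of the IZH family, IZH1, IZH3 and IZH4 were tested and 0 passed (IZH4 fell adjusted over the list alone), and IZH2 itself had a log2 fold change of -0.75 (adjusted p = 0.40), which ran from -1.18 without the first to -0.32 without the second eos1 deletion array and was -0.47 without the first wild-type array.

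Growth-related lists lay below the median of all genes while few of their members passed on their own. Camera called 6 such lists at the preset correlation, and with an estimated correlation each had an adjusted p of 0.715. Of 60 ribosome biogenesis genes 0 passed (1 fell without the second wild-type array), and 7 fell after median centring, among them NHP2 and BRX1. Their median was -0.42 relative to all genes (camera, adjusted p = 2.7e-11). Of 127 cytosolic ribosomal protein genes 1 fell, RPS9A, and the list's median was -0.26 (camera, adjusted p = 9.7e-09), a call lost after quantile normalization (adjusted p = 0.65). The amino acid synthesis genes controlled by Gcn4, with medians of -0.32 over 33 genes (adjusted p = 4.0e-06), included HIS1 and ILV3, and 0 passed (3 fell after median centring and 3 without the first eos1 deletion array). In methionine and sulfur assimilation 1 of 18 genes fell, SAM3, by 3.05-fold (adjusted p = 0.013), and the list's median was -0.31 (camera, adjusted p = 0.00080). That median was -0.53 without the first eos1 deletion array, -0.20 without the second and -0.16 without the second wild-type array. Glycolysis and ethanol formation (median -0.29 over 16 genes, adjusted p = 0.0021) and fatty acid synthesis (median -0.35 over 11 genes, adjusted p = 0.013) were also called lower with 0 members called. The glycolysis call was lost after quantile normalization (adjusted p = 0.63), without the second wild-type array (median -0.16, adjusted p = 0.27) and without the first eos1 deletion array (median -0.19, adjusted p = 0.061). The fatty acid call was lost after quantile normalization (adjusted p = 0.090), without the second wild-type array (adjusted p = 0.17) and without the second eos1 deletion array (adjusted p = 0.0501). Adjusted over the list alone, 1 ribosomal protein gene fell, 4 methionine and sulfur genes fell and 1 rose, and 0 genes of the other 4 lists passed. Of the members with the smallest p in these lists, ENP1, UTP20, RPL19A, RPL19B, MET8, PDC5, ACB1 and FAA1 lay higher. On leaving out single arrays their log2 fold changes lay between 0.08 (FAA1) and 1.00 (PDC5). The others, NHP2, BRX1, RPS9A, RPL4B, SAM3, MMP1, MET16, PFK1, PFK2, TDH3, FAA3, ELO1, HIS1, HIS5, ILV3 and LEU1, lay lower.

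**Figure D3:**
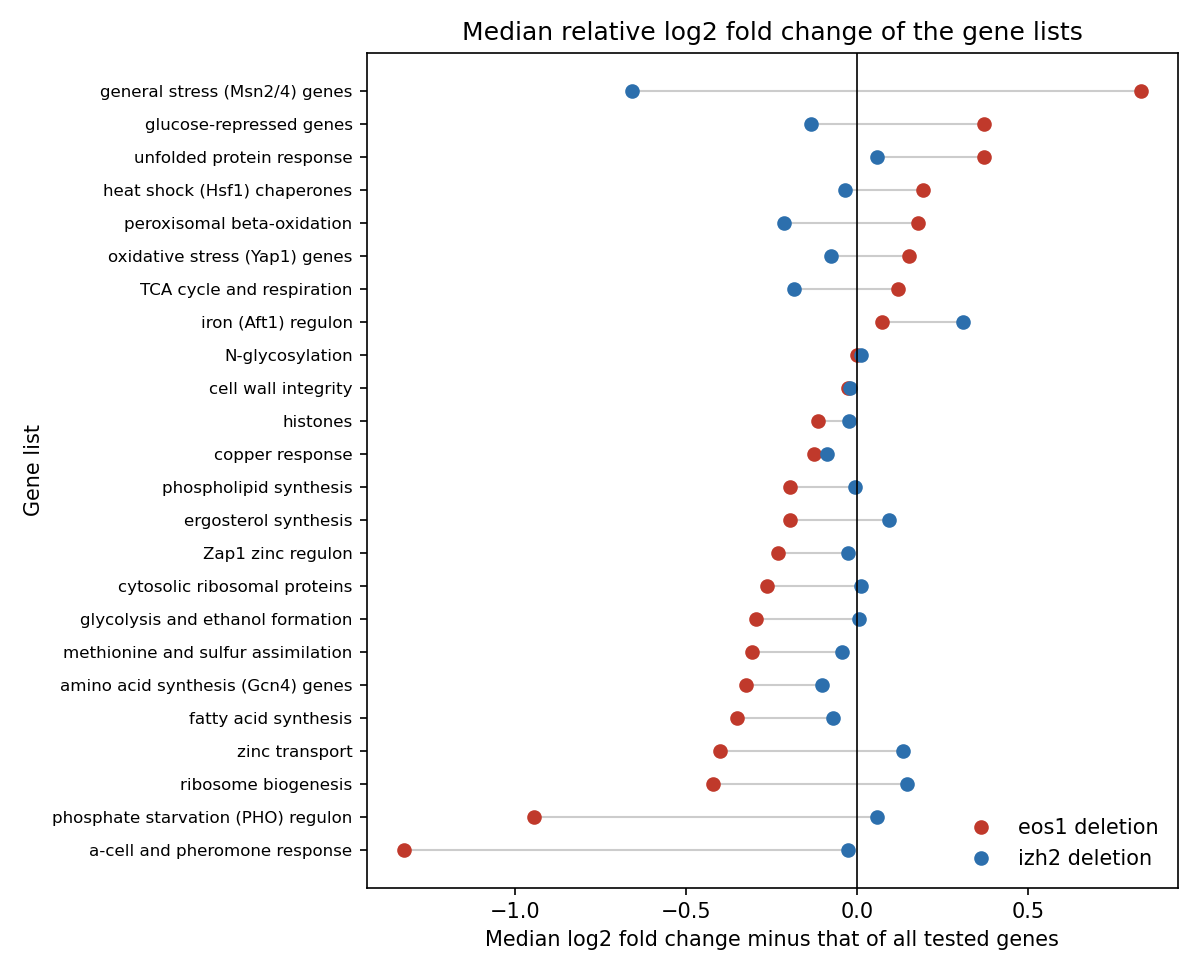
Median log2 fold change of each gene list against wild type, minus the median of all tested genes (horizontal axis), for the lists with at least 5 tested members (vertical axis), with red points for the eos1 deletion and blue points for the izh2 deletion. The general stress genes lie at 0.83 in the eos1 deletion and -0.66 in the izh2 deletion, and the a-cell list lies at -1.33 and -0.03.

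The second comparison asked the same of loss of IZH2. Apart from IZH2 itself, 0 genes passed an adjusted p under 0.05 (limma), with 105 genes, IZH2 among them, at an unadjusted p under 0.05, of which 8 were higher and 97 lower. The median of all genes was 0.11 lower on the log2 scale, and after median centring IZH2 was again the 1 gene to pass, with 113 genes at an unadjusted p under 0.05. Both counts lie below a share of 0.05 of the 4907 tested genes, which is what no effect would give. They are therefore no sign of further changes. Without the second wild-type array 25 genes passed. The lowest unadjusted p values among genes other than IZH2 belonged to TMA17, with a log2 fold change of -1.12 (SE 0.20, adjusted p = 0.57), and RTC3, with -1.44 (SE 0.28, adjusted p = 0.69). Without the second wild-type array RTC3 passed, at -1.60 (adjusted p = 0.0060). Those of HSP42, HXK1, YOR385W and AIM17 lay between -1.56 and -1.11, and that of GSY1 was -1.003. On the higher side, the glucose repressor genes MIG1 and MIG2 had log2 fold changes of 0.80 and 0.70, the cyclin gene CLB2 0.69, and YGR079W, HLR1, NRM1, HST3 and FTR1 between 0.57 and 0.79.

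Camera called 10 of 24 lists in the izh2 deletion, and with an estimated correlation 0, with 0.91 the smallest adjusted p. The smallest adjusted p that fry gave there, on median-centred values, was 0.59, for ribosome biogenesis. General stress genes had the lowest median, -0.66 relative to all genes (camera, adjusted p = 2.4e-20; adjusted p = 0.91 with an estimated correlation). Of the 26, 0 passed, and 7 fell adjusted over the list alone. HXK1 had a log2 fold change of -1.56, DDR2 -1.28, HSP42 -1.17 and GLK1 -0.78. Without the first izh2 deletion array they had -2.27, -1.68, -1.35 and -1.06 and the list a median of -0.82, and without the second -0.86, -0.88, -0.99 and -0.50 and a median of -0.44. Without the second wild-type array DDR2 passed (-1.47, adjusted p = 0.040). Genes of the TCA cycle and respiration, such as COX6 (-0.53) and QCR9 (-0.56), had a median of -0.18 over 42 genes, or -0.11 without the second izh2 deletion array (camera, adjusted p = 5.3e-06; adjusted p = 0.91 with an estimated correlation). Genes of the iron regulon controlled by Aft1 lay higher, with a median of 0.31 over 23 genes (camera, adjusted p = 1.8e-08; adjusted p = 0.91 with an estimated correlation). The siderophore transporter gene SIT1 had a log2 fold change of 0.98, the reductase gene FRE4 0.97, and FTR1, the iron permease, 0.62. The values of SIT1, FRE4 and the list rested largely on 1 array. Without the second izh2 deletion array SIT1 had 0.25, FRE4 0.23 and the list a median of 0.02. Without the first they were 1.72, 1.71 and 0.62. FTR1 moved less, from 0.45 to 0.79 on leaving out single arrays. Ribosome biogenesis had a median of 0.15 over 60 genes (camera, adjusted p = 5.5e-06; adjusted p = 0.91 with an estimated correlation; adjusted p = 0.071 without the second wild-type array).

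Camera called 5 further lists lower and 1 higher in the izh2 deletion, with adjusted p from 0.026 to 0.048. These were the ribosomal proteins, the cell wall integrity, oxidative stress and amino acid synthesis genes and peroxisomal beta-oxidation on the lower side and ergosterol synthesis on the higher. In all of them 0 members passed, over all genes or adjusted over the list alone, and every call was lost without the second wild-type array and, with an estimated correlation, at adjusted p from 0.91 to 0.94. The ribosomal protein list had a median and a mean of 0.01 relative to all genes, against the direction of its test. The direction of 3 of these lists turned on leaving out 1 array. The amino acid list, with a median of -0.10, had -0.35 without the first izh2 deletion array (adjusted p = 1.5e-10), 0.09 without the second, where camera called it higher (adjusted p = 0.048), -0.16 without the first and -0.04 without the second wild-type array. The cell wall list, with -0.02, had -0.18 without the first and 0.11 without the second wild-type array, and -0.12 without the first and -0.05 without the second izh2 deletion array. The ribosomal protein list had 0.12 without the first izh2 deletion array, where camera called it higher (adjusted p = 0.020), -0.09 without the second, -0.04 without the first and 0.07 without the second wild-type array. Of the others, the oxidative stress list (-0.08) had -0.12 without the first izh2 deletion array, beta-oxidation (-0.21) -0.14 and ergosterol synthesis (0.09) 0.04 without the first wild-type array, and ergosterol synthesis 0.17 without the second. Members with the smallest p were RPL41A (-0.78), PIR3 (-0.83), PRX1 (-0.54), ARG1 (-1.30) and FOX2 (-0.59) in the lower lists and ERG5 (0.40) in the higher one. On leaving out single arrays ARG1 ran from -2.49 to -0.11, RPL41A from -1.35 (adjusted p = 0.039, without the second wild-type array) to -0.21, PIR3 from -1.35 to -0.31, PRX1 from -0.74 to -0.33 and FOX2 from -0.88 to -0.29. The lowest and highest came from leaving out an izh2 deletion array, except for RPL41A, where they came from leaving out a wild-type array. After median centring the ribosomal protein, cell wall integrity, oxidative stress and amino acid synthesis lists were not called (adjusted p of 0.37, 0.095, 0.067 and 0.067). Without the second izh2 deletion array the cell wall (adjusted p = 0.28), oxidative stress (0.31) and beta-oxidation (0.28) lists were not called. Without the first the ergosterol (0.12) and beta-oxidation (0.054) lists were not. Without the first wild-type array the oxidative stress (0.053), beta-oxidation (0.11) and ergosterol (0.43) lists were not, and without the second eos1 deletion array the ribosomal protein list was not (0.051).

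The Zap1 regulon gave no call in the izh2 deletion. Its 23 tested members had a median log2 fold change of -0.13, or -0.03 relative to all genes, with 0 members called over all genes or adjusted over the list alone (camera, adjusted p = 0.63, in the direction of higher expression, against the sign of the median). CTT1 had a log2 fold change of -0.76, ZAP1 0.49, YJL132W -0.36 and TSA1 -0.18. ZRT1 had a signal of 1127 ± 43.2 (SD, n = 2), against 1110 ± 270 in the wild type. Fry of limma, on median-centred values, gave an adjusted p of 0.90. The phosphate starvation list had a median of 0.06 (adjusted p = 0.58) and the a-cell list of -0.03 (adjusted p = 0.89), with 0 members called in either.

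The deletions were then set against each other, a contrast in which the wild-type arrays take no part except in the estimate of the spread. It called 617 genes, 582 higher in the eos1 deletion and 35 lower, with a shift of the median of all genes of 0.31. After median centring it called 517, 325 higher and 192 lower, of which 360 were among the 617. Besides the deleted genes, HSP26 (18.8-fold), DDR2 (18.3-fold) and RTC3 (13.0-fold) were the highest in the eos1 deletion. PHO11 (14.1-fold), PHM6 (8.69-fold) and SPL2 (8.08-fold) were the lowest. DDR2 was 12.1-fold higher without the first and 27.7-fold without the second eos1 deletion array. Chromosome II held 270 of the higher calls. Of the 26 general stress genes 25 were higher in the eos1 deletion (22 after median centring, 25 adjusted over the list alone), with a median of 1.46 relative to all genes (camera, adjusted p = 1.4e-17; adjusted p = 0.485 with an estimated correlation). Of the a-cell list 10 of 14 were lower (camera, adjusted p = 1.2e-22; adjusted p = 0.125 with an estimated correlation), and of the phosphate starvation list 6 were lower and 1 higher (camera, adjusted p = 5.4e-21; adjusted p = 0.15 with an estimated correlation). ZRT1 was 2.07-fold lower in the eos1 than in the izh2 deletion (adjusted p = 0.017), a call lost on leaving out any 1 of the eos1 or izh2 deletion arrays, with adjusted p from 0.055 to 0.15. Without the second izh2 deletion array 8 general stress genes were higher, and 3 genes of the a-cell list and 3 of the phosphate starvation list were lower. Without that array 75 genes passed over all, without the first 284, and without the first eos1 deletion array 276.

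No gene was called in both deletions against the wild type, in the same or in opposite directions. Since IZH2 itself was the 1 gene called in the izh2 deletion, this could hardly have come out otherwise. It does not show that the responses differ. Across 4905 genes, which are not independent replicates, the log2 fold changes of the deletions correlated at Pearson r = 0.06 and Spearman rho = 0.12. Both comparisons share the wild-type arrays, and 100 simulated sets with no effect and the same sharing gave r = 0.50 ± 0.01 (SD). The covariance was 0.0071 against a simulated 0.0327, a difference of -0.0256. The simulated arrays varied independently. Deviations of same-numbered arrays correlated at 0.48 between wild type and eos1 deletion and at -0.34 between wild type and izh2 deletion. The simulated values are thus not an exact reference. They hold for 2 arrays per strain and do not apply where 1 array is left out. The observed correlation was 0.44 without the second wild-type array and 0.24 without the first eos1 deletion array. It took the other sign, -0.13, without the second eos1 deletion array.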

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

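Of the tests in this part, those of array scaling, alpha cells and growth stage were chosen only after the result was seen. Camera called the general stress genes in both deletions in opposite directions, and the contrast of the deletions, which tests that difference, gave a median log2 difference of 1.78, or 1.46 relative to all genes (camera, adjusted p = 1.4e-17). The ribosome biogenesis genes were likewise called in opposite directions, with a median difference of -0.28, or -0.59 relative to all genes (camera, adjusted p = 3.8e-20). With an estimated correlation the adjusted p values of these differences were 0.485 and 0.429. Among 192 probe sets that name no gene and pass the filter, 16 were called higher and 0 lower in the eos1 deletion, or 12 and 3 after median centring. The strongest of them, a reporter probe set of the array (RPTR-Sc-AJ002682-1_s_at), was also the 1 called higher in the izh2 deletion: its signals were 6.22 and 8.10 in the wild type, 13964 and 13371 in the eos1 deletion and 11515 and 12828 in the izh2 deletion. What sequence it probes is not given in the sources used here.

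The first pattern weighed is the excess of chromosome II genes in the eos1 deletion. A scaling factor moves all genes of an array alike, so it leaves this excess unchanged (0.85 before and after median centring). The excess of 0.88 after quantile normalization was therefore largely fixed beforehand and is not counted as evidence. A bias that depends on signal strength is argued against by excesses of at least 0.60 in all 5 classes of mean signal. A candidate explanation that met its test is a second copy of the whole of chromosome II in most cells of the eos1 deletion cultures: in 17 stretches of at least 20 neighbouring genes the excess ran from 0.65 to 1.00. It remains a hypothesis, since DNA was not measured, and whether such a copy would follow from the loss of EOS1 or be peculiar to the strain used was not tested. Other changes in the eos1 deletion arrays, those of genes on other chromosomes too, are open to the same explanation.

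The second pattern is the fall of a-cell genes in the eos1 deletion. Diploid cells would lower haploid-specific genes alike, but STE4, STE5, STE18, RME1, NEJ1 and AXL1 had a median of 0.0053 relative to all genes. They ran from -0.56 (STE4) and -0.26 (AXL1), in the direction diploid cells would give, to 0.32 (NEJ1), while 6 a-specific genes ran from -1.12 to -3.22. These haploid-specific genes were taken from outside the fixed list. Within that list 10 of 14 genes fell, not only the 6 a-specific ones. FUS1 is among them, and diploid cells could lower it too. Alpha cells are argued against by the alpha-factor precursor gene MF(ALPHA)1, whose signal was at most 0.80 of the background of the eos1 deletion arrays, although no array here shows that its probe set can respond; FUS1, which both haploid cell types express, also fell, and a share of alpha cells would lower the a-specific genes alike. Other alpha-cell genes lay higher. SAG1 had 0.46 relative to all genes (log2 fold change 0.67, limma, adjusted p = 0.099). STE3, which did not pass the filter, had signals of 47.2 and 45.3 in the wild type. In the eos1 deletion its signals were 144 and 121, against backgrounds of 15.2 and 11.9. A response to the loss of EOS1 or to chromosome II stays open and was not tested.

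The third pattern is the rise of general stress genes in the eos1 deletion. A later growth stage at harvest cannot be told apart. Glucose-repressed genes had a median of 0.37 relative to all genes, with an adjusted p of 0.715 (camera with an estimated correlation). That test could hardly be met with these arrays: 0 lists were called by it in the eos1 deletion, with 0.14 the smallest adjusted p. The labels give an optical density of 1.0 for all cultures together, not for each. A biological response to the loss of EOS1 stays open, and so does a response to extra chromosome II genes as a whole.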

How the results depend on the processing

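Fits without chromosome II genes were chosen after the data were seen; all other alternatives were fixed beforehand. Of 125 results for named genes, 15 alternatives gave 1840 values, of which 1772 kept direction and side of the threshold, 32 passed it newly, 21 no longer passed and 15 reversed. Of the results for the izh2 deletion against the wild type, only that of IZH2 passed in the main fit. Many of the others lay too far from the threshold to cross it. The tally is therefore high in part by construction and does not measure how stable the calls were. The cause of a change was not tested unless one is stated. Fits without chromosome II genes test fewer genes, and their adjustment also loses the chromosome II calls. For the eos1 deletion against the wild type (349 genes called), 224 passed with only the 4 arrays compared, 144 by a 2-fold rule in all pairs without a test, 59 without chromosome II genes and 100 without them after centring, where fewer genes are tested; leaving out single arrays gave 159 (first eos1 deletion array) to 413, with 224 and 225 without the first and second izh2 deletion array. For the izh2 deletion (1) the stricter filter gave 0, since it removes IZH2 itself, the 2-fold rule 2, and leaving out arrays 1 to 25 (second wild-type array). For the contrast of the deletions (617) the stricter filter gave 405, the 2-fold rule 245, and the fits without chromosome II genes 250 and, centred, 228; leaving out arrays gave 75 (second izh2 deletion array) to 875, with 276 without the first eos1 and 284 without the first izh2 deletion array. The labels do not say whether same-numbered arrays share more than a number: deviations correlated at 0.48 (wild type and eos1 deletion), -0.34 (wild type and izh2 deletion) and 0.09 (the deletions), and with the replicate number as a block 426, 1 and 736 genes passed in the 3 comparisons. Lists called fell from 12 to 0 in the eos1 deletion with an estimated correlation (10 to 14 leaving out arrays), and from 10 in the izh2 deletion to 6 after centring, 6 with the stricter filter and 0 with an estimated correlation (3, without the second wild-type array, to 12). The Zap1 median (eos1 deletion, -0.02) reversed to 0.042 with no filter and ran from -0.17 to 0.21 leaving out arrays, above 0 without the first wild-type or the second eos1 deletion array, with adjusted p from 0.0039 to 0.13 (the latter array); in the izh2 deletion (-0.13) it reversed to 0.015 after quantile normalization and ran from -0.18 to -0.04. The correlation of the deletions (0.06) was 0.049 after quantile normalization, 0.13 with no filter, 0.093 without chromosome II genes, -0.0030 with the stricter filter and -0.13 (second eos1 deletion array) to 0.44 (second wild-type array) leaving out arrays, with 0.24 without the first eos1 and 0.016 without the first izh2 deletion array. Reversals of uncalled genes, after quantile normalization and after centring, were SWS2 (-0.14 and -0.13) and TPM1 (-0.078 and -0.17) in the eos1 deletion and ERG10 (0.0085 and 0.016) and PHO80 (0.037 and 0.037) in the izh2 deletion. Leaving out arrays gave -0.28 to 0.49 for SWS2, -0.14 to 0.27 for TPM1, -0.20 to 0.041 for PHO80, -0.79 to 0.062 for HIS3 and -0.21 to 0.27 for EOS1 in the izh2 deletion. The chromosome II excess ran from 0.83 to 0.88 over the 15 alternatives that keep these genes and fit all results. With 90.1% of genes above the filter, dim genes such as STE3 and MF(ALPHA)1 were left without a test in the main fit. They entered the fit with no filter, whose values for them are not given here.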

Other observations

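Lists that camera did not call in the eos1 deletion with all arrays still held called members, named here after their values were seen. Of 22 oxidative stress genes 3 rose, the mitochondrial peroxiredoxin gene PRX1 (4.49-fold) and the transporter gene FLR1 (2.76-fold), both on chromosome II, and the regulator gene YAP1 (1.97-fold), and the list had an adjusted p of 0.37. In cell wall integrity the glucan synthase gene GSC2 rose 4.05-fold, CHS3, on chromosome II, and YPS3 rose, and CWP1 fell 2.44-fold, out of 15 genes (adjusted p = 0.41). In the iron list FTH1, on chromosome II, ARN1 and HMX1 rose out of 23 genes (adjusted p = 0.38), and in respiration ATP3, COR1 and CIT1 rose out of 42 (adjusted p = 0.069), the first and second of these on chromosome II. Of 13 glucose-repressed genes PCK1, ACH1, on chromosome II, and HXK1 rose and MAE1 fell (adjusted p = 0.18), of 21 heat shock chaperones HSP26, on chromosome II, and HSP78 rose (adjusted p = 0.069), and of 8 beta-oxidation genes FAA2 rose (adjusted p = 0.37). Copper response, ergosterol synthesis, phospholipid synthesis and histones had 0 called members and adjusted p from 0.22 to 0.37, with 1 phospholipid gene higher without the second eos1 deletion array and 1 histone gene lower without the first. Some of these lists were called under other settings. Ergosterol synthesis was called lower after median centring (adjusted p = 0.035) and without the first wild-type array (0.044). Respiration was called higher without the second eos1 deletion array (0.012), without the first or the second izh2 deletion array (0.035 and 0.032) and without chromosome II genes (0.042). The iron list was called higher without the first eos1 deletion array (0.0039). Heat shock chaperones were called higher without that array (0.026), without the second wild-type array (0.047) and without the first or the second izh2 deletion array (0.030 and 0.032). The TCA cycle and respiration list and the heat shock (Hsf1) chaperones were also called higher after quantile normalization (0.0028 each) and with the stricter filter (0.013 and 0.015), and the glucose-repressed genes with no filter (0.024). All of these calls used the preset correlation. With an estimated correlation 0 lists were called in the eos1 deletion under any of these settings, and ergosterol synthesis had an adjusted p of 0.45 after median centring and 0.80 without the first wild-type array. Adjusted over the list alone, 3 oxidative stress, 5 cell wall, 3 iron, 3 respiration, 6 glucose-repressed, 3 heat shock and 1 beta-oxidation genes rose, 1 cell wall and 1 glucose-repressed gene fell, and 0 genes of the other lists named here passed. Without the first eos1 deletion array 2 oxidative stress, 2 cell wall, 0 iron, 0 respiration, 0 glucose-repressed, 1 heat shock and 0 beta-oxidation genes rose, and CWP1 was not called. Without the second eos1 deletion array 1 iron, 5 glucose-repressed and 3 heat shock genes rose, and MAE1 was not called. Without the first wild-type array 1 cell wall gene rose, and without the second 5 cell wall and 0 beta-oxidation genes did. Without 1 of the izh2 deletion arrays, the first or the second, 1 heat shock and 0 beta-oxidation genes rose. After median centring 2 oxidative stress, 2 cell wall, 1 iron, 3 respiration, 1 glucose-repressed, 1 heat shock and 0 beta-oxidation genes rose.

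In the izh2 deletion the lists that camera did not call, apart from those already described, were zinc transport, copper response, the unfolded protein response, N-glycosylation, heat shock chaperones, phospholipid synthesis, fatty acid synthesis, methionine and sulfur assimilation, glycolysis, glucose-repressed genes and histones, with adjusted p from 0.093 to 0.89 and 0 called members in each. Several of these depended on 1 array. Without the first izh2 deletion array methionine and sulfur assimilation (0.014), fatty acid synthesis (0.034) and glucose-repressed genes (0.048) were called lower and heat shock chaperones higher (0.022). Without the second, heat shock chaperones (3.5e-07) and glycolysis (0.00097) were called lower, and without the first wild-type array heat shock chaperones (0.015), glycolysis (3.0e-05) and glucose-repressed genes (0.040) were. With an estimated correlation 0 lists were called in the izh2 deletion on leaving out any array. Without the second wild-type array 1 glycolysis gene fell. Adjusted over the list alone, 1 heat shock and 1 glucose-repressed gene fell. Between the deletions camera called 17 lists, 5 higher and 12 lower in the eos1 deletion, and 0 with an estimated correlation. After quantile normalization camera with an estimated correlation called 1 list between the deletions (adjusted p = 0.044).

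Within the ribosomal protein genes RPS9A stood alone among the calls in the eos1 deletion, at a log2 fold change of -2.04 while the list's median was -0.05. Other falls outside the fixed lists, singled out after their values were seen, were the a-cell gene ASG7 (-1.63), the purine genes ADE17 (-1.41), SHM2 (-1.09), AAH1 (-0.93) and ADE6 (-0.80), and the oxygen-regulated genes ANB1 (-1.33) and TIR3 (-1.28). No list of purine or oxygen-regulated genes was fixed or tested.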
